A study of Homo sapiens with 12 samples.

How the data were processed

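RNA was sequenced from A549 cells, a human lung adenocarcinoma line, that stably carried a lentiviral TIF1γ (TRIM33) expression construct, an shRNA against TAF15, or the matching control construct. The labels list 12 samples, 3 biological replicates in each of 4 groups. A processed file was available for 8 of them: vector replicates 1, 2 and 3, TIF1γ replicates 2 and 3, sh-NC replicate 2, and sh-TAF15 replicates 2 and 3. The other 4 samples are not analysed here. Per the labels, total RNA with a RIN above 6.5 was converted to libraries after poly(A) selection or ribosomal RNA removal and run on an Illumina HiSeq instrument. Per the labels, the reads were handled with cutadapt 1.9.1, HISAT2 2.0.1 and HTSeq 0.6.1 against the GRCh37 genome.

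The deposited values are FPKM (fragments scaled to transcript length and to the mapped total), with no logarithm, and how the authors computed them from the reads is not stated. Each file holds 57879 Ensembl gene identifiers, of which 52324 were matched to a symbol and 5555 were not, and the latter are named by identifier. The reference at hand is GRCh38 with GENCODE 29, so it served for names, gene types, transcript length and transcript GC percent, and no GRCh37 coordinates are given. No read totals come with the values, so the sequencing depth behind them is unknown and no counting interval or floor is given.

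For 19 genes an exact 0 in at least 1 library stood beside 100 FPKM or more in another. These may be failed estimates of the software that made the values, so the genes were set aside from every test (11 of them would have passed the filter). Genes with at least 1 FPKM in at least 2 of the 8 libraries were kept, which left 13907 genes. The values were scaled by a trimmed mean of log2 ratios to the mean of all libraries, over genes at 1 FPKM or more in all 8 (30% of ratios and 5% of abundances trimmed at each end). A pseudocount of 1 was added before the log2, which draws the fitted fold changes of weakly expressed genes toward 0.

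The plan written before the data were examined named a model for read counts. As the files at hand hold no counts, it was replaced by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust set) on log2(FPKM + 1), with all 4 groups in 1 fit and no covariate. The fit has 4 residual degrees of freedom and a prior of 9.57. The lone sh-NC library is assumed to vary like the libraries of the other groups. The contrasts tested were TIF1γ minus vector, sh-TAF15 minus sh-NC, the difference between these effects, and sh-NC minus vector. P values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 is a call. Overlaps of calls were tested with a one-sided Fisher's exact test. On simulated data with the measured spread, independent normal noise and no GC trend, 200 genes were changed by known amounts. They were drawn from genes with a mean log2 value of at least 2, so recovery of weaker genes was not measured. All 200 were changed at once in each simulation, which eases the Benjamini-Hochberg threshold. Recovery can thus be lower where fewer genes change. The fit recovered 36.8% of genes changed by 1 log2 unit and 97.0% of those changed by 2 log2 units for TIF1γ, and 10.3% and 93.9% for sh-TAF15, with 17 and 14 false calls.

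The 28 gene lists were written before the data were examined, and the 27 with at least 3 tested members were tested. They cover mesenchymal and epithelial markers of the epithelial-mesenchymal transition (EMT), TGF-beta SMAD targets, IL6 JAK STAT3, NF-kB and interferon genes, and TFIID and TBP complex subunits. They further cover FET family RNA-binding proteins, TRIM family and SMAD4 partners, S phase, G2 and M phase, p53, unfolded protein and ATF4, NRF2, hypoxia, and cholesterol genes. The rest are extracellular matrix, adhesion receptors, receptor tyrosine kinase and MAPK feedback, histones, lineage markers (alveolar and airway, fibroblast, leukocyte, endothelial, neuroendocrine), mitochondrial mRNAs, ribosomal proteins, and abundant noncoding RNAs. Each list was compared with all other genes by camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry were run beside it.

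Genes were named by a rule written before the data were examined. It takes the targeted genes, further fixed genes (among them IL6, CDH1, CDH2, VIM, FN1, SNAI1, SNAI2, ZEB1, SMAD4, TBP and EWSR1), and up to 8 genes per direction with the largest change among calls. Those had to have a symbol that is not a clone name, a mean of at least 2 FPKM, and every treated library beyond every control library. The 3 members of each list with the lowest adjusted p are also named. For sh-NC against vector the rule took only the largest changes among calls. Fixed genes, list members and other genes named there lie outside it. Elsewhere, genes outside the rule are marked where they appear. Transcript GC percent and length were set against the fold changes. A trend in both was removed from each library by loess (span 0.3, degree 1) as an alternative. Other alternatives were median ratio scaling, no further scaling, scaling to an equal sum, 2 other filters and none, pseudocounts of 0.1 and 0.5, protein-coding genes only, the set-aside genes kept in (for gene lists too), the replicate number as a block, each comparison's own groups only, and each library left out in turn. Figures were drawn with matplotlib 3.10.9.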

Results

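Gene expression was measured by RNA sequencing in A549 cells with TIF1γ overexpression, with TAF15 knockdown, and with the matching empty or non-targeting construct. TIF1γ, encoded by TRIM33, is a ubiquitin ligase of the TRIM family that acts on SMAD4 and TGF-beta signalling. TAF15 is an RNA-binding protein of the FET family and was first described as a TBP-associated factor. The values cover 3 vector, 2 TIF1γ, 1 sh-NC and 2 sh-TAF15 libraries. The sum of FPKM per library ran from 881293 in vector replicate 1 to 1356634 in TIF1γ replicate 2. Between 18580 and 19620 genes per library had a value above 0, and between 12132 and 12622 reached 1 FPKM. Depth in reads is not known. For sh-NC only 1 library is at hand, so its values carry no SD. The first principal component held 61.6% of the variance and set the 3 sh libraries apart from the vector and TIF1γ libraries.

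**Figure D1:**
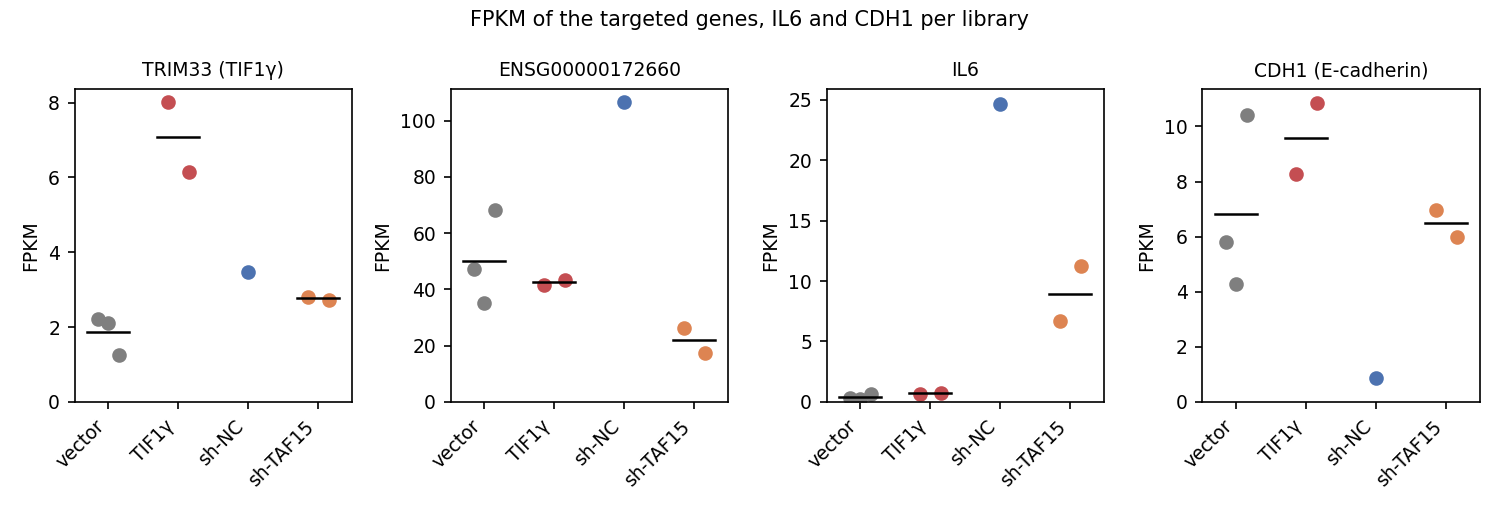
FPKM (y axis, linear from 0) of TRIM33, ENSG00000172660, IL6 and CDH1 in each library (points) by group (x axis), with the mean of groups of more than 1 library as a line. TRIM33 stands at 8.03 and 6.14 in the TIF1γ libraries and at 3.46 or less in the others, and IL6 at 0.737 or less in the vector and TIF1γ libraries and at 24.7 in sh-NC.

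The first comparison asks how the transcriptome of A549 cells differs when TIF1γ is overexpressed. TRIM33 (ENSG00000197323) stood at 7.08 ± 1.34 FPKM (SD, n = 2) in TIF1γ libraries against 1.86 ± 0.522 (SD, n = 3) in vector, and both TIF1γ libraries lay above all 3 vector libraries. Transcripts of the G2 and M phases of the cell cycle fell as a group, with 33 of 40 tested members below 0 and a median log2 fold change of −0.64 (camera adjusted p = 1.31e-07). S phase transcripts fell as a group too, with 31 of 39 below 0 and a median of −0.32 (camera adjusted p = 6.32e-04). Epithelial markers of the EMT rose as a group, with 13 of 18 above 0 and a median of 0.62 (camera adjusted p = 0.00717). That list leaves out the keratin genes KRT8 and KRT18, which are high in vector and listed at 0 in both TIF1γ libraries, and with them kept in it was not called (20 members, median 0.58, adjusted p = 0.502). The calls rest on camera in its setting with the preset inter-gene correlation. The adjusted p was 0.884, 0.886 and 0.884 with an estimated correlation.

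TRIM33 had a log2 fold change of 1.46 (SE 0.27), with an adjusted p of 0.13 over all genes and 0.00157 adjusted over the list alone. Of the 14 fixed genes 0 were called by limma over all genes, 1 was called adjusted over the list alone, and 2 had an unadjusted p under 0.05. SMAD4, the TGF-beta mediator that TIF1γ binds, had 4.88 ± 0.385 FPKM (SD, n = 2) in TIF1γ libraries and 8.22 ± 1.48 (SD, n = 3) in vector (log2 fold change −0.71, adjusted p = 0.207). With the GC and length trend removed, its log2 fold change was −0.23 (limma adjusted p = 0.821). CDH1, CDH2, VIM, FN1, SNAI1, SNAI2 and ZEB1, the classical EMT genes, had adjusted p values from 0.407 to 0.952. IL6 was at 0.691 ± 0.0646 FPKM (SD, n = 2) against 0.4 ± 0.24 (SD, n = 3), with an adjusted p of 0.599.

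Among G2 and M phase genes, 17 passed in the negative direction when adjusted over the list alone and 0 over all genes. ANLN, an actin-binding protein of the cleavage furrow, stood at 4.32 and 3.96 FPKM in the TIF1γ libraries and at 17.0, 19.8 and 6.39 in vector. The spindle proteins CKAP2L and NUSAP1 had log2 fold changes of −1.20 (SE 0.29) and −0.99 (SE 0.24), each with an adjusted p of 0.2. In S phase, 7 genes passed over the list alone. RRM1, a subunit of ribonucleotide reductase, went with −1.12 (SE 0.25), POLE2 of DNA polymerase epsilon with −1.32 (SE 0.34), and the clamp loader subunit RFC3 with −1.07 (SE 0.30). The mean log2 level of the G2 and M phase list was 4.91, 4.91 and 4.28 in vector replicates 1, 2 and 3, and 4.19 and 4.03 in the TIF1γ libraries, so vector replicate 3 lay next to the TIF1γ libraries. For the S phase list it was 4.79, 4.76 and 4.25 in vector and 4.48 and 3.91 in the TIF1γ libraries, so TIF1γ replicate 2 lay above vector replicate 3.

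Among epithelial markers, 7 genes passed in the positive and 1 in the negative direction over the list alone, and 0 over all genes. CLDN7, a tight junction claudin, stood at 6.59 ± 0.0726 FPKM (SD, n = 2) against 2.5 ± 0.424 (SD, n = 3), and KRT19, a simple epithelial keratin, at 61.6 ± 0.171 against 33.1 ± 7.61. TJP1, the tight junction protein ZO-1, had a log2 fold change of −0.92 (SE 0.30). Subunits of TFIID and the TBP complex fell as a group, with 21 of 24 below 0 and a median of −0.41 (camera adjusted p = 0.00717). Here the adjusted p was 0.884 with an estimated correlation. GTF2F2, TAF9B and TAF7 had log2 fold changes of −0.93, −0.89 and −0.65, with adjusted p values of 0.2, 0.2 and 0.212. Mitochondrially encoded mRNAs had a median of 0.30, with 13 of 13 above 0 and an adjusted p of 0.117.

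The other lists were not called. The adjusted p was 0.0554 for FET family proteins, 0.127 for TRIM and SMAD4 partners, 0.127 for ribosomal proteins, 0.129 for alveolar and airway markers, and 0.179 for NF-kB genes, cholesterol synthesis and histones. It was 0.251 for mesenchymal markers, 0.323 for leukocyte and neuroendocrine markers, 0.47 for MAPK feedback, 0.502 for TGF-beta SMAD and NRF2 targets, and 0.504 for hypoxia. The remaining values were 0.602 for IL6 JAK STAT3 genes, the unfolded protein response and adhesion receptors, 0.617 for extracellular matrix, 0.618 for interferon genes, fibroblast markers and noncoding RNAs, and 0.873 for p53 targets. For adhesion receptors the median was 0.05 and the mean −0.13. Only 2 endothelial markers reached the filter, too few for a test.

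Over single genes, limma called 2 genes higher and 1 lower of 13907, and 2771 (19.9%) had an unadjusted p under 0.05, where 695 would be expected by chance. With the GC trend removed that number was 936, with a replicate block 923, and with 1 library left out it ran from 1039 (without TIF1γ replicate 2) to 4209 (without TIF1γ replicate 3). Of the 3 called genes, 0 are annotated as protein-coding, and ENSG00000269804 has no annotated type. SNORA53, a small nucleolar RNA (ENSG00000212443), was at 7.91 ± 5.73 FPKM (SD, n = 2) in the TIF1γ libraries and listed at 0 in the other 6 (adjusted p = 0.00237). With the GC trend removed, SNORA53 was no longer called (adjusted p = 0.103). NANOGP1, a pseudogene of NANOG (ENSG00000176654), was at 5.59, 3.48 and 5.33 in vector and listed at 0 elsewhere (adjusted p = 0.00197). ENSG00000269804, named outside the rule, was at 7.39 and 3.76 in TIF1γ, 4.02 in sh-NC, and listed at 0 elsewhere (adjusted p = 0.00197). Leaving out 1 library changed the count, to 7, 18 and 285 without vector replicate 1, 2 and 3, and to 1 and 13 without TIF1γ replicate 2 and 3. The 285 comprised 94 higher and 191 lower, and a fit with the replicate number as a block gave 44.

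The TIF1γ fold changes followed the base composition of the transcripts. Across 11720 protein-coding genes, the Spearman rho between log2 fold change and transcript GC percent was 0.797 (genes are not independent replicates). It was 0.428 for TAF15 knockdown, 0.465 for the difference between both effects and −0.481 for sh-NC against vector. The median log2 fold change was −0.60 in genes under 40% GC and 0.49 in those above 60%. Vector replicate 3 differed from vector replicates 1 and 2 in the same direction, with a rho of 0.47 and 0.33. Between vector replicates 2 and 1 the rho was 0.085. After this trend was removed from each library, the G2 and M phase list had a median of −0.31 (camera adjusted p = 5.89e-06), the S phase list −0.29 (2.74e-05) and the epithelial list 0.25 (0.026). The TFIID list was no longer called (0.127), whereas mitochondrial mRNAs had a median of 0.51 (2.74e-05) and cholesterol synthesis genes −0.17 (0.0149). For all 5 lists called after the removal, the adjusted p was 0.936 with an estimated correlation.

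**Figure D2:**
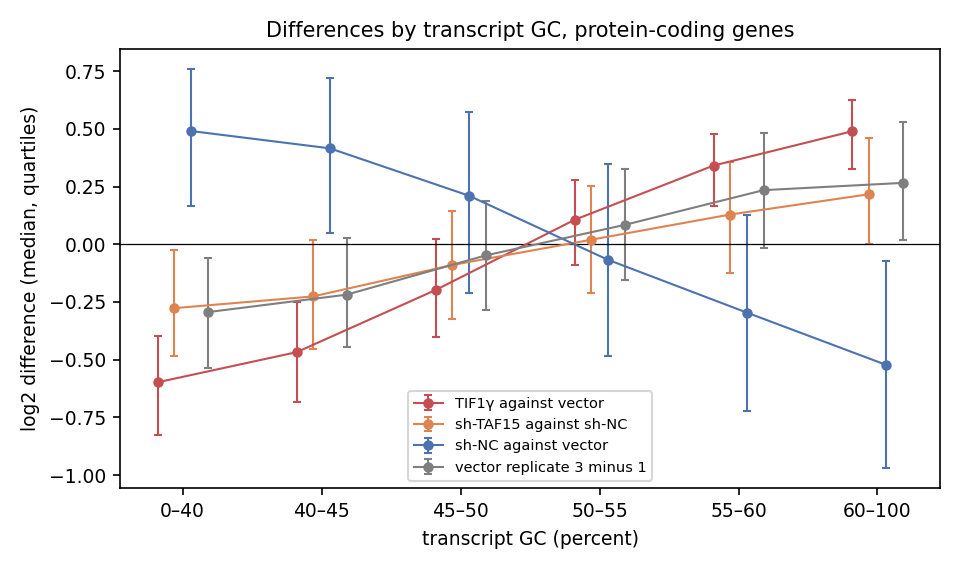
Median log2 difference (y axis, points, with quartiles as bars) of protein-coding genes by transcript GC percent (x axis, 6 classes) for 3 comparisons and for vector replicate 3 minus replicate 1. The TIF1γ values go from −0.60 to 0.49, the sh-NC values against vector from 0.49 to −0.52.

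The second comparison asks how the transcriptome differs when TAF15 is silenced. The current identifier of TAF15 is not in the values. ENSG00000172660, which has no name in the annotation used and is recalled as the older identifier of TAF15 without a way to verify it here, stood at 21.9 ± 6.27 FPKM (SD, n = 2) in sh-TAF15 against 107 in sh-NC. Targets of NRF2, the transcription factor of the oxidative stress response, rose as a group, with 24 of 31 above 0 and a median of 0.26 (camera adjusted p = 0.00254). Feedback genes of receptor tyrosine kinase and MAPK signalling fell as a group, with 22 of 28 below 0 and a median of −0.30 (camera adjusted p = 0.00479). Epithelial markers rose as a group with a median of 0.34, and genes of the unfolded protein and ATF4 response fell with a median of −0.33 (camera adjusted p = 0.0252 for each). In this order, the adjusted p was 0.684, 0.766, 0.766 and 0.905 with an estimated correlation.

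ENSG00000172660 had a log2 fold change of −2.33 (SE 0.41), with an adjusted p of 0.0669 over all genes and 0.000864 adjusted over the list alone. IL6, the inflammatory cytokine, was at 6.67 and 11.3 FPKM in sh-TAF15 and 24.7 in sh-NC (log2 fold change −1.46, SE 0.39), and its adjusted p was 0.32 over all genes and 0.0108 over the list alone. CDH1, which encodes E-cadherin, was at 6.48 ± 0.676 (SD, n = 2) against 0.857 (log2 fold change 1.92, SE 0.46), with 0.23 over all genes and 0.00684 over the list alone. Of the 14 fixed genes 0 were called by limma over all genes, 3 were called adjusted over the list alone, and 4 had an unadjusted p under 0.05. EWSR1, an RNA-binding protein, had a log2 fold change of −0.21 (SE 0.34), and TRIM33 had −0.29 (SE 0.36).

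In the NRF2 list, the glutathione peroxidase GPX2 stood at 1.89 and 2.01 FPKM against 0.0758 in sh-NC, far under the 781 ± 197 (SD, n = 3) of vector. The aldehyde dehydrogenase ALDH3A1 was at 1612 and 1989 against 568, and the aldo-keto reductase AKR1C2 at 264 and 262 against 124.5. In the MAPK list, the ERK phosphatase DUSP5 was at 12.6 ± 1.84 (SD, n = 2) against 38.0 and the AP-1 subunit FOSL1 at 71.4 ± 0.997 against 136, with SPRED3 at 0.417 and 0.056 against 1.51. Of the epithelial markers 13 of 18 were above 0 and 2 passed over the list alone. The protease inhibitor SPINT2 was at 173 ± 51.3 (SD, n = 2) against 63.4 and the junction protein JUP at 12.1 ± 0.14 against 4.68. In the unfolded protein and ATF4 list, 28 of 35 were below 0. ATF4 had a log2 fold change of −0.75 (SE 0.43), the cystine transporter SLC7A11 −0.83 (SE 0.49) and the asparagine synthetase ASNS −1.19 (SE 0.70). Over all genes, 0 members of these 4 lists were called by limma, and DUSP5 had the lowest adjusted p, 0.126.

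The other 23 lists had adjusted p values from 0.0565, for G2 and M phase genes and for adhesion receptors, to 0.783. In matrix and mesenchymal genes, the matricellular protein SPARC had a log2 fold change of −1.27 (SE 0.37), and THBS1, thrombospondin 1, −1.64 (SE 0.35), whereas the smooth muscle actin ACTA2 had 1.12 (SE 0.40), the laminin subunit LAMA5 0.89 (SE 0.35) and FN1 1.08 (SE 0.50). Their adjusted p values were 0.461, 0.149, 0.695, 0.755 and 0.889, and the extracellular matrix list had 15 members above 0 and 15 below. With the GC trend removed, the epithelial list was no longer called (adjusted p = 0.097), while mesenchymal markers (0.0232) and adhesion receptors (0.0286) were called in the negative direction. For these 2 lists the adjusted p was 0.663 and 0.898 with an estimated correlation. Median and test differed in sign for p53 targets (median −0.03), extracellular matrix (0.01) and leukocyte markers (0.15).

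Over single genes, limma called 7 genes higher and 1 lower of 13907, and 782 had an unadjusted p under 0.05, where 695 would be expected by chance. The 782 became 574 with a replicate block and 938 with the GC trend removed. LGALS9C (ENSG00000171916) and LGALS9B (ENSG00000170298), paralogs of the galectin-9 gene, rose by 2.75 (SE 0.43) and 2.58 (SE 0.38) log2 units. LGALS9C was at 9.67 and 6.04 FPKM against 0.194, and LGALS9B at 7.42 and 10.3 against 0.517 (adjusted p = 0.0351 and 0.0204). MSANTD3-TMEFF1 (ENSG00000251349), a readthrough transcript, was at 3.92 and 3.93 against 0.0101 (adjusted p = 0.0425). With the GC trend removed, LGALS9C, LGALS9B and MSANTD3-TMEFF1, the only protein-coding calls, were no longer called. The pseudogenes ATP5MKP1 (46.0 and 18.0 FPKM) and HSPB1P1 (11.2 and 17.1), and, outside the naming rule, AL161787.1 (25.6 and 59.8) and ENSG00000202077 (49.8 and 37.9), were listed at 0 in the other 6 libraries. AC004890.2, also outside the rule, fell from 7.92 to 0.348 and 0.444. The count was 17 without vector replicate 1, 49 without vector replicate 2, and 4 without vector replicate 3 or either TIF1γ library. It was 176 with the sh libraries alone in the fit and 52 with a replicate block.

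The difference between both effects was tested with each manipulation against its own control. It compares fold changes and not expression levels, as sh-NC itself differed from vector in 1529 called genes. MAPK feedback genes (median of the difference 0.23, camera adjusted p = 4.97e-04) and mesenchymal markers (0.36, adjusted p = 0.0037) had a higher fold change under TIF1γ than under TAF15 knockdown. So did unfolded protein and ATF4 genes (0.41, 0.0116), mitochondrial mRNAs (0.38, 0.0277) and hypoxia genes (0.19, 0.0469). G2 and M phase genes (−0.40, adjusted p = 0.00173), NRF2 targets (−0.25, 0.0307) and S phase genes (−0.31, 0.0389) had a lower fold change under TIF1γ. In the same order, the adjusted p was 0.722, 0.656, 0.889, 0.889, 0.656, 0.889, 0.662 and 0.889 with an estimated correlation. With the GC trend removed, hypoxia, G2 and M phase and S phase genes were no longer called (adjusted p = 0.0969, 0.0541 and 0.0969), with medians of 0.20, −0.19 and −0.23 after the removal. A replicate block ended the calls of NRF2 targets, hypoxia genes and mitochondrial mRNAs. Limma called 6 single genes, 2 higher and 4 lower, and 501 had an unadjusted p under 0.05, fewer than the 695 expected by chance (1147 without vector replicate 3).

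**Figure D3:**
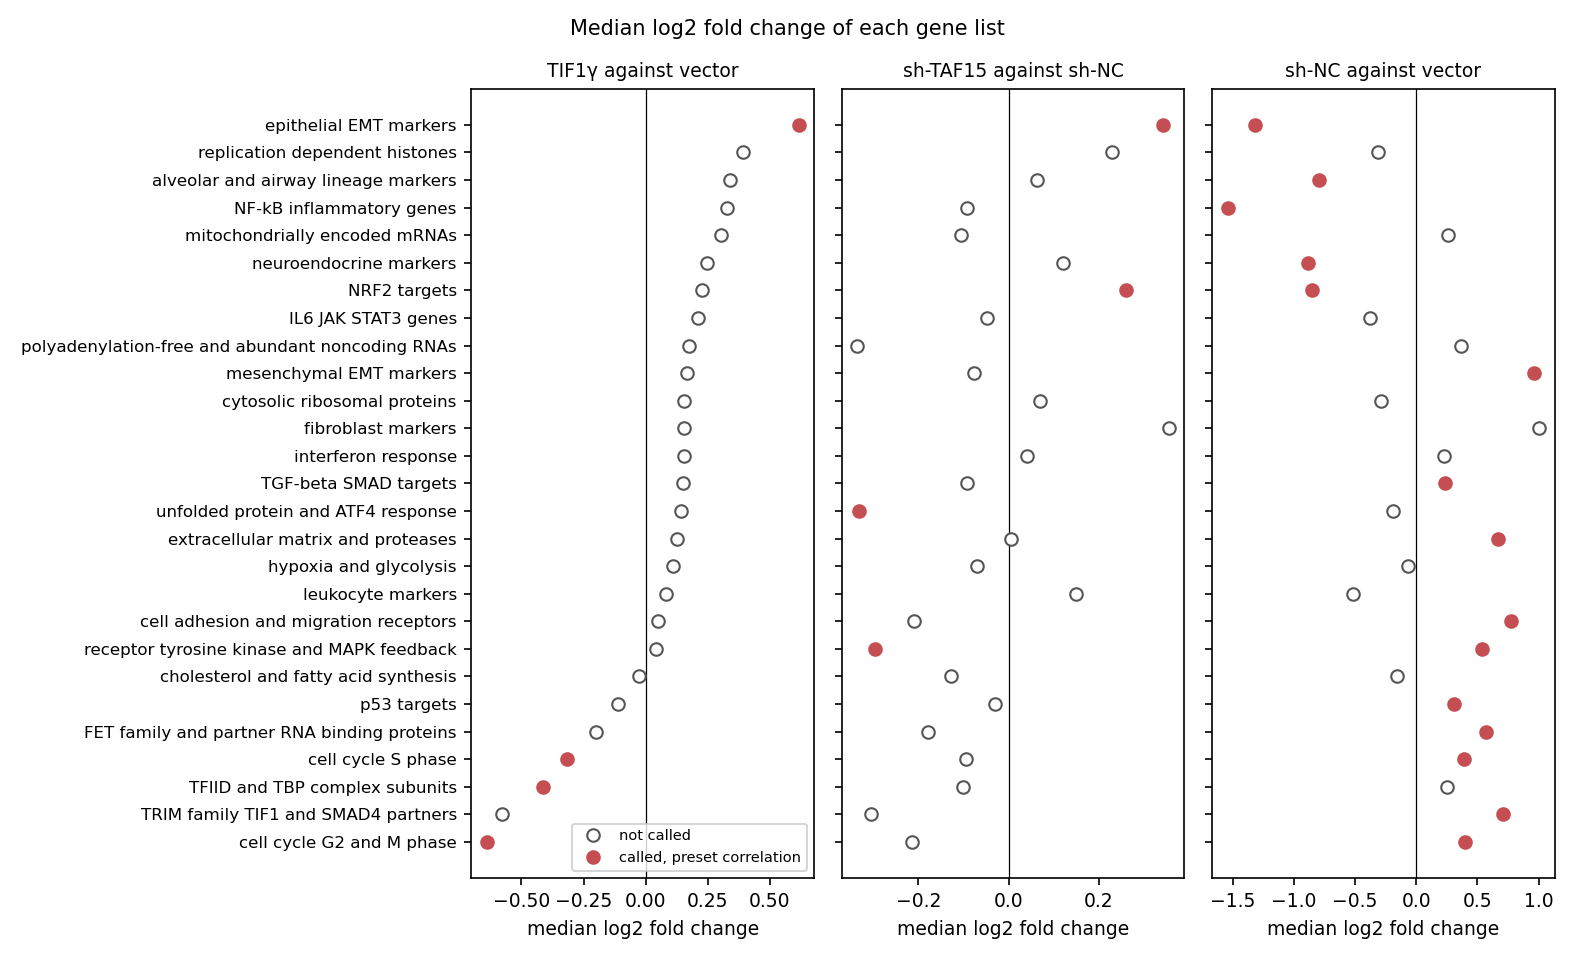
Median log2 fold change (x axis) of the tested members of 27 gene lists (y axis) in 3 comparisons, with lists called by camera at the preset correlation filled. The G2 and M phase list has the lowest median under TIF1γ, −0.64, and in 0 of the 3 panels is a list called with an estimated correlation.

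Both manipulations were then set side by side. No gene was called by limma in both, 0 of the 3 and 8. At an unadjusted p under 0.05, 121 genes were higher in both where 42.3 would be expected if the effects were independent, and 61 were lower in both where 32.6 would be (one-sided Fisher's exact test, p = 1.81e-27 and 8.20e-07, genes not being independent). In opposite directions, 11 and 8 genes were found where 24.4 and 56.5 would be expected. Both sets of fold changes rose with transcript GC percent (rho 0.797 and 0.428), and such a common trend by itself favours shared directions. The overlap was not tested again with the trend removed, so it cannot be told apart from that trend. Across 13907 genes the log2 fold changes had a Pearson correlation of 0.388 and a Spearman correlation of 0.446. The Pearson values of the 4 pairings of 1 TIF1γ with 1 sh-TAF15 library had an SD of 0.095. With the GC trend removed, the correlations were 0.216 and 0.258, and the SD of the pairings was 0.0727.

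The sh-NC library was compared with vector to see how far both control lines differ. Targets of NRF2 fell (27 of 31 below 0, median −0.85), as did NF-kB inflammatory genes (22 of 26, median −1.54) and epithelial markers (17 of 18, median −1.32). Mesenchymal markers rose (21 of 25 above 0, median 0.96). GPX2 was at 658, 678 and 1008 FPKM in vector and 0.0758 in sh-NC, and KRT19 at 33.1 ± 7.61 (SD, n = 3) and 0.243. MMP2, a matrix metalloproteinase, was at 1.16 ± 0.509 (SD, n = 3) in vector and 25.5 in sh-NC, and IL6 at 0.4 ± 0.24 and 24.7.

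By limma, 526 genes were higher and 1003 lower in sh-NC, 1272 of the 1529 being protein-coding and 1517 changed at least 2-fold. The largest falls under the naming rule were GPX2, the Na,K-ATPase regulator FXYD2 (−8.42, SE 0.31), the synaptic protein CPLX2 (−6.86, SE 0.41) and IGFL2-AS1 (−6.09, SE 0.39). The largest rises were the carboxypeptidase CPA4 (5.00, SE 0.37), RPS27P9 (listed at 0 in vector and 25.1 FPKM in sh-NC), the annexin ANXA10 (4.51, SE 0.33) and IL6 (4.11, SE 0.37). Of the 14 fixed genes 5 were called over all genes and 8 adjusted over the list alone. CDH1 fell by 2.12 and FN1, fibronectin, fell by 2.10 on the log2 scale, while CDH2, N-cadherin, rose by 1.66 and the EMT transcription factor SNAI2 by 2.50.

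In the lists, 11 epithelial genes were called lower over all genes and 0 higher, among them JUP and SPINT2 (log2 fold changes −3.97 and −3.35). NF-kB genes had 16 called lower, among them the chemokines CXCL5, CXCL1 and CCL2 (−5.70, −4.20 and −3.21), and NRF2 targets 11, among them AKR1C2 and AKR1B10 (−5.14 and −3.93). Mesenchymal genes had 10 called higher and 3 lower. The camera adjusted p was 1.30e-09 for NRF2 targets and for NF-kB genes, 5.84e-08 for epithelial and 1.27e-06 for mesenchymal markers, and the adjusted p was 0.0901, 0.441, 0.255 and 0.0901 with an estimated correlation.

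A further 11 lists were called. Extracellular matrix (adjusted p = 8.98e-04), FET family proteins (0.0016), S phase (0.00286), MAPK feedback (0.0101), adhesion receptors (0.0106), TRIM and SMAD4 partners (0.0126), G2 and M phase (0.0206), TGF-beta SMAD targets (0.0341) and p53 targets (0.0487) rose. Neuroendocrine (0.00106) and alveolar and airway markers (0.00181) fell. In this order, the adjusted p was 0.441, 0.441, 0.765, 0.573, 0.765, 0.441, 0.829, 0.765, 0.765, 0.255 and 0.4 with an estimated correlation. The basement membrane collagens COL4A1 and COL4A2 rose by 2.84 and 2.34 log2 units, the fibulin FBLN1 by 2.19 and FOSL1 by 2.27, while the matrix metalloproteinase MMP7 fell by 5.42. HNF4A, a transcription factor of liver and gut endoderm, was at 5.39 ± 1.59 FPKM (SD, n = 3) in vector and listed at 0 in sh-NC (adjusted p = 3.67e-04). With the GC trend removed, G2 and M phase genes were no longer called (adjusted p = 0.337). Fibroblast markers (4 tested members, median 1.24 after the removal) were then called higher, though not with an estimated correlation. With no further scaling of the values, 899 genes were called higher and 782 lower, so which direction has more calls depends on the scaling. This comparison rests on 1 sh-NC library against 3 vector libraries.

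**Figure D4:**
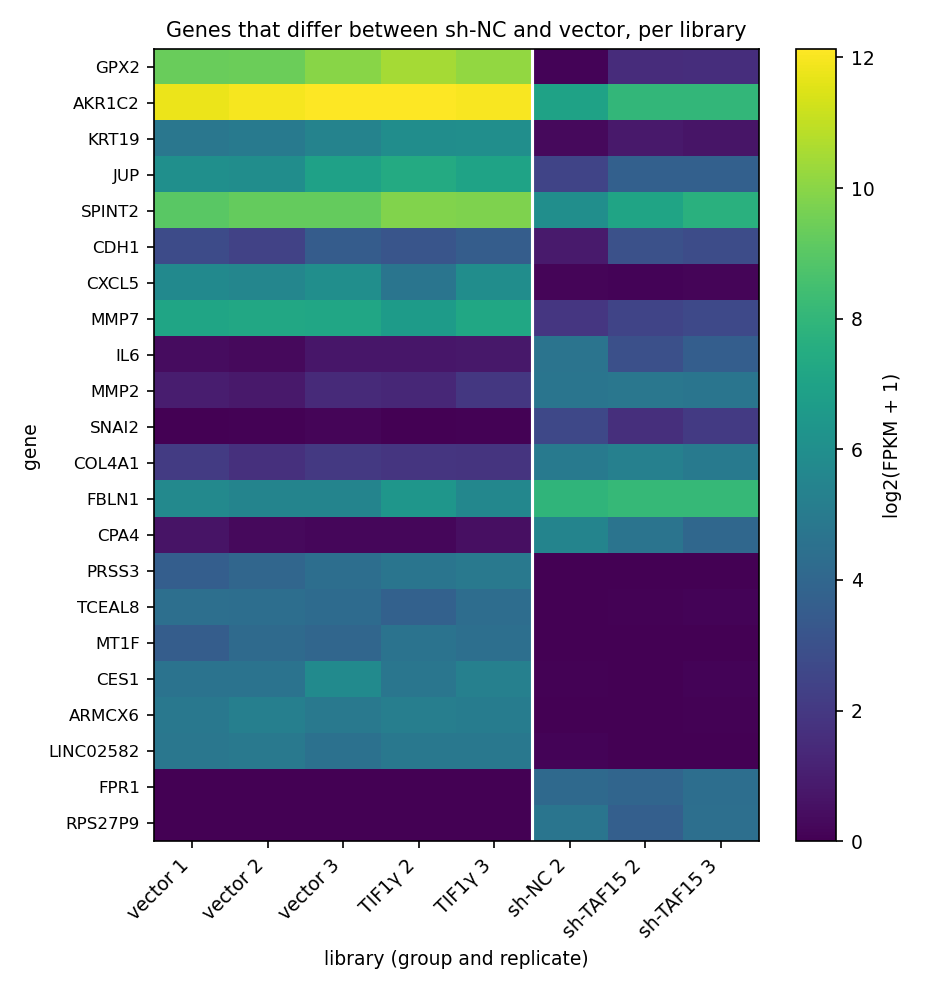
Expression as log2(FPKM + 1) (colour) of 22 genes (y axis) in the 8 libraries (x axis), vector and TIF1γ left of the white line and sh libraries right of it. GPX2 is at 658 FPKM or more in the 5 libraries on the left and at 2.01 or less in the 3 on the right, and MMP2 is at 2.94 or less on the left and at 24.8 or more on the right.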

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

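The tests on base composition, on MTAP, on genes that separate the libraries, on admixed cells and on the distance to vector were chosen after the results were seen, and the test without a shared library was written before its result. In limma, 6 genes differed between the TIF1γ effect and the TAF15 knockdown effect by a test of the difference itself. ENSG00000202077 (adjusted p = 0.000137), AL161787.1 (0.000761), ATP5MKP1 (0.00322) and HSPB1P1 (0.00322) had values in both sh-TAF15 libraries and were listed at 0 in the other 6. ENSG00000269804 (adjusted p = 0.00042) had values in both TIF1γ libraries and in sh-NC and was listed at 0 in the other 5. AC004890.2 (adjusted p = 0.0162) was at 7.92 FPKM in sh-NC and at 1.46 or less in the other 7 libraries. All 6 were called with a fold that depends on values at or near 0, and 0 of them are annotated as protein-coding, with no annotated type for ENSG00000202077 and ENSG00000269804.

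The first pattern is that TIF1γ fold changes rose with transcript GC percent, a trend that the other comparisons show too (rho 0.428 for TAF15 knockdown and −0.481 for sh-NC against vector). Vector replicate 3 differed from vector replicates 1 and 2 with a Spearman rho of 0.47 and 0.33 over the same genes, and replicates 2 and 1 with 0.085. A library bias that is unrelated to the construct, seen among vector libraries mainly in replicate 3, is thus a candidate explanation. A response to TIF1γ cannot be told apart from it with 2 libraries against 3, although the lowest rho of a TIF1γ library exceeded the highest of a vector library by 0.195. Whether the GC and length trend is the whole cause of the lower G2 and M phase transcripts is also open. After its removal the lowest vector library lay −0.242 log2 units from the highest TIF1γ library, an overlap, and the median log2 fold change went from −0.64 to −0.31.

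The second pattern is the difference between sh-NC and vector. The GC and length trend is argued against as the whole cause, because 1057 of the 1529 called genes were called in the same direction after its removal. A swap for a line that keeps MTAP, a gene recalled as deleted in A549 cells, is argued against by at most 0.578 FPKM of MTAP in the 3 sh libraries, although CDKN2A, recalled as deleted with it, was at 1.895 FPKM in sh-TAF15 replicate 3 (0 in the other 2 sh libraries). Another stock or clone of the line, another line that lacks MTAP, or another library batch stays open. None of these can be told apart from the constructs, since the sh constructs and the set of libraries coincide. The 8 genes on in every library of 1 set and off in every library of the other were picked for that split, so they do not bear on its cause, and no biological explanation was tested.

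The third pattern is that the sh-TAF15 libraries lay between sh-NC and vector, with a covariance of −0.225 between the knockdown and the control fold changes (−0.170 with the GC trend removed), which share the sh-NC library. Cells of the vector line mixed into the sh-TAF15 libraries are argued against. The 35 genes under 0.5 FPKM in sh-NC and at 10 or more in vector gained a median of 0.339% of the vector level, and the other 968 lower genes gained 21.5%. Simulated chance values gave a covariance of −0.121 (lowest of 100, −0.129), short of the measured one, but the simulation takes the spread of sh-NC from the other groups. Without a shared library the covariances were −0.106 and −0.00300. With the GC trend removed they were −0.0574 and 0.0082, so chance stays open. A response to TAF15 knockdown may also contribute and cannot be told apart from chance with 1 sh-NC library, which lay 0.0912 log2 units (root mean square) farther from vector than the farther sh-TAF15 library.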

How the results depend on the processing

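The tests with pseudocounts of 0.1 and 0.5, an equal sum, set-aside genes kept in, protein-coding genes, a mean FPKM of at least 5 and the GC and length trend removed were chosen after the data were seen. The planned scalings and filters were adapted from counts to FPKM, and DESeq2 and limma-voom were not run, as the files at hand hold no counts. TIF1γ calls (3) became 0 with no filter (2952 at unadjusted p under 0.05), with protein-coding genes (2723) and with a mean of at least 5 (2064), 5 at pseudocount 0.1 and with set-aside genes, and 44 with a replicate block (923 unadjusted). With the trend removed 936 had an unadjusted p under 0.05. TAF15 calls (8) became 188 with no filter (19 higher, 169 lower), 1 with at least 1 FPKM in 3 libraries, 52 with a replicate block, 176 with own groups only, 21 at pseudocount 0.1, 15 with protein-coding genes, 18 with a mean of at least 5 and 3 with the trend removed. The equal sum gave 5 higher and 2 lower. Calls of the difference (6) became 103, 2, 30, 0 (395 unadjusted) and 3 with no filter, 3 libraries, the replicate block, protein-coding genes and a mean of at least 5. With no filter 97 were higher and 6 lower. The equal sum gave 1 higher and 4 lower. The sh-NC calls (1529) became 1000 with a replicate block and ranged from 1125 to 1700 otherwise. With 1 library left out, the 4 counts ranged from 1 to 285, 4 to 49, 3 to 18, and 1198 to 1700.

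For calls shared by both comparisons (0) the values were 1 with median ratio scaling, no scaling, an equal sum or set-aside genes, 4 with a replicate block, and 0 to 2 with 1 library left out. For the correlation of fold changes across genes (0.388) they were 0.292 at pseudocount 0.1, 0.216 with the trend removed, and 0.255 to 0.432 with 1 library left out. Lists called fell from 4, 4 and 15 to 0, 0 and 0 with an estimated correlation (0, 1 and 4 unadjusted) and to 0, 0 and 7 with fry (2, 2 and 12 unadjusted). The estimate was 0.011 for mesenchymal markers and 0.0213 for NRF2 targets, near the preset 0.01. For these lists, correlation among the members does not alone account for the lost calls, as the 4 residual degrees of freedom enter too. With the replicate block, the calls were lost of TFIID subunits under TIF1γ (adjusted p = 0.0611), of epithelial markers under TAF15 knockdown (0.101), of G2 and M phase genes in sh-NC (0.112), and of NRF2 (0.0693), hypoxia (0.0836) and mitochondrial (0.146) genes in the difference. The block added calls of adhesion receptors under TAF15 knockdown, in the negative direction, and of NF-kB genes in the difference, in the positive direction. With set-aside genes kept in, the epithelial call under TIF1γ was lost (0.502). No scaling moved the median of all genes to 0.16 for sh-NC, and an equal sum to 0.18 for sh-NC and −0.13 for TIF1γ. No called list changed the sign of its median under these scalings. TRIM33 stayed between 1.27 and 1.93 over 19 settings (adjusted p 0.0441 to 0.601) and ENSG00000172660 between −2.64 and −2.01 (4.34e-05 to 0.337). No named gene's direction reversed under the alternatives run. Replicate numbers may pair vector and TIF1γ libraries, but only 2 pairs exist (r = 0.171 and 0.121), so the replicate block stays an alternative. Depth is unknown, so values near 0 set no floor.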

Other observations

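The genes named here were chosen after their values were seen. They were taken as those at 10 FPKM or more in every library of 1 set and under 0.1 FPKM in every library of the other set, the sets being the 5 vector and TIF1γ libraries and the 3 sh libraries. PRSS3, a trypsinogen, was at 11.5 FPKM or more in the vector and TIF1γ libraries and listed at 0 in the 3 sh libraries. MT1F, a metallothionein, was at 11.1 to 23.3 and listed at 0. The carboxylesterase CES1 was at 23.5 to 54.2 against 0.0788 or less, and the X-linked genes ARMCX6 and TCEAL8 at 28.0 to 36.1 and 12.5 to 20.8 against 0.0414 and 0.0711 or less. LINC02582 was at 21.9 to 29.2 against 0.0947 or less. In the other direction, FPR1, a receptor for formylated peptides, was at 14.3 to 20.1 in the sh libraries against 0.0284 or less, and the pseudogene RPS27P9 at 11.9 to 25.1 against 0. Exact zeros of PRSS3, MT1F and RPS27P9 carry the same doubt as those of FTL below, since no read counts are at hand.

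KRT8 and KRT18, the simple epithelial keratin pair, and FTL, the ferritin light chain, are among the 19 genes set aside. KRT8 was at 5036, 5747 and 5307 FPKM in vector, listed at 0 in both TIF1γ libraries, and at 1397, 1855 and 2235 in the sh libraries. KRT18 was at 5092, 5721 and 4561, listed at 0 in both TIF1γ libraries, and at 1129, 1540 and 2158. FTL was listed at 0 in the 5 vector and TIF1γ libraries and at 14970, 21770 and 33399 in the sh libraries. No value in these data shows whether the zeros are failed estimates.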
